A study of Lactococcus lactis with 32 samples.

How the data were processed

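RNA of *L. lactis* KF147 from 2 retentostats and 10 days was labelled with Cy3 and Cy5 and hybridised in pairs to 32 arrays on 4 slides of 8 arrays, in a loop with shortcuts (per the labels). Per the labels, cells were quenched in cold methanol buffer and broken with beads, and RNA was extracted with phenol and chloroform and enriched for mRNA. Per the file headers, the deposited scanner files hold the mean spot and local background intensity of each channel, neither background-subtracted nor normalised, with spot quality codes whose meaning is not given in the sources used here. The deposited series matrix holds a Cy5 over Cy3 ratio per probe. From its values, the authors had subtracted the background and corrected an intensity-dependent dye bias within each array: over bright probes the ratio follows the scanner files' own ratio up to a smooth function of intensity, with a residual spread of 0.00024 to 0.00591. Its values are on a linear scale, and the column medians of 0.851 to 1.05 show that the columns are not centred exactly.

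Each array has 15744 features: 10772 gene probes, 4436 blank features and 536 controls. The gene probes belong to 2770 genes, 1598 of them with 5 probes, and the probe names give the locus, a symbol where there is one and the probe's position in the gene. Of these genes 2424 have a locus number, and 346 are open reading frames named after gene-finding programs. The reference table holds another strain and 0 of the locus tags are in it, so symbols come from the probe names alone, and genes sharing a symbol are given by locus. A gene counted as above background in an RNA sample when any of its probes, on any array of that sample, exceeded the 99th percentile of the blank features. For the naming rule, passing in either culture was enough for a day. As a measure of depth, 62.2% to 99.8% of gene probes exceeded that level in Cy5 and 78.1% to 99.8% in Cy3. Precision depends on the number of cultures as well as of arrays.

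Signals were background-corrected by normexp with an offset of 50, normalised within arrays by loess and averaged over the probes of a gene in R 4.3.3 with limma 3.58.1. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Culture, not array, is the replicate, with n = 2 per day. The log2 ratios of each gene were fitted with a coefficient per day and 1 dye term, by generalised least squares in which each RNA sample adds a variance shared by its arrays. The ratio of that variance to the array variance, estimated once for all genes by restricted maximum likelihood, was 0.319 (0.827 over 28 arrays), and the whitened ratios went into limma (moderated, two-sided, Benjamini-Hochberg over 2770 genes, threshold 0.05). The median residual SD of a gene was 0.250. Comparisons were day 42, 2, 7, 14, 21, 28 and 35 with day 0, an F test over these 7, day 43 with 42, day 44 with 43 and with 42, and retentostat 2 with 1. Of 33 gene lists taken from symbols and product names, 31 had members, and they were tested with camera (preset correlation 0.01, and an estimated correlation beside it), adjusted over lists within a comparison. Members were matched by patterns of symbols, and those of transposases and of polyketide and nonribosomal peptide synthesis gave none. This reflects how the lists were written, since symbols such as pksA, pksB and nrpB are on the arrays. The locus from pksA onward was therefore not tested as a list.

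The naming rule was set at the same time as the tests and lists. It names, for day 42 with day 0, day 43 with 42 and day 44 with 43, up to 10 genes with the largest changes each way among those called, with the same sign in both cultures and above background on both days, and the 3 members with the smallest p of each list past its test. For day 2 and for the cultures it names 5 each way, for the F test 5 genes, and where fewer than 5 genes are called the 5 with the smallest p. The rule was also applied to the 28 arrays.

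Samples of the same number come from the same vessel. Deviations of consecutive days from their day means correlated across genes at 0.161 to 0.632 within a culture, above 0.1 in 9 of 9 pairs of days. Consecutive days of a culture share arrays, which can give such a correlation by itself, and no simulated reference was made for it. Retentostat as a block is given beside the results. Arrays of slide 4 include the 4 set apart. The loop closes only across slides, so most comparisons could not be fitted within 1 slide. The results do not adjust for slide, and a dye term per slide is an alternative. Days 2, 7 and 14 against day 0 were also fitted on slide 3 alone, day 14 against day 0 on slide 4 alone, and days 43 and 44 on slide 2 alone, with 4, 5 and 1 residual degrees of freedom and the variance ratio of the fit over 32 arrays.

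The fit was tested on simulated data with the same layout, with 100 genes changed 2-fold and 100 changed 4-fold among 2770. These data were drawn from the fitted model itself, with normal errors, independent RNA samples and no trend with brightness or probe position. A rate near the nominal level among unchanged genes was thus built in, and the test does not show that the real data follow the model. It recovered 48 and 96 of them for day 42 with day 0, where 4.86% of unchanged genes had a p below 0.05, and 81 and 100 for day 43 with day 42, where 5.56% did. When the 4 arrays were simulated to carry no difference between their RNAs, 0 and 1 were recovered for day 42 with day 0 over 32 arrays, and 25 and 87 over 28 arrays. The median estimate was then 0.62 of the true change over 32 arrays and 0.98 over 28.

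Alternatives set beforehand were no background correction, a normexp offset of 0, median centring, scaling of arrays to the same spread, leaving out dim probes (7106 probes of 2174 genes kept), the median of probes, the authors' ratios (2531 genes, centred per array), no dye term, a dye term per slide, retentostat as a block, a 2-stage fit of the 20 sample estimates, arrays as the only error, array weights, no moderation, a 2-fold minimum, other days for the cultures, and leaving out each RNA sample in turn. Leaving out the 4 arrays, with and without the block, the fits within a slide and the reversal without the brightness trend were added after seeing the data.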

Results

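Transcript levels of *Lactococcus lactis* subsp. *lactis* strain KF147, a plant isolate, were measured in 2 independent anaerobic retentostats. In a retentostat a filter holds the cells back while spent medium leaves, so that growth slows towards 0 under a constant, limiting supply of glucose. Each vessel was started from a chemostat at a dilution rate of 0.025 per h on a defined medium with 25 mM glucose at 30 °C. It was sampled in the chemostat (day 0) and on days 2, 7, 14, 21, 28, 35, 42, 43 and 44. The resulting 20 RNA samples, 1 per culture and day, were compared in pairs on 32 two-colour arrays, with 2 to 4 arrays per RNA sample. Of these arrays, 22 compared days within a culture and 10 compared the cultures with each other. Values were obtained for 2770 genes, of which 2544 to 2769 lay above background in an RNA sample, counted by any probe on any array. Precision depends on the number of cultures as well as of arrays.

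On 4 arrays, all on the same slide, the log2 ratios spread less (SD 0.176 to 0.205 across genes) than on the other 28 (0.267 to 0.701). Their correlation with the ratios that the other arrays predict was −0.02 to 0.04, against 0.19 to 0.84. They were retentostat 1 day 14 over day 0, retentostat 1 day 42 over day 21, and the ratios of the cultures on days 28 and 35. Counts are therefore given for all 32 arrays and, as a choice made after seeing the data, for the other 28. Simulated with no difference on these 4 arrays, day 42 changes reached a median 0.62 of their true size over 32 arrays. Over the 28 they reached 0.98. The day 42 changes given over 32 arrays may thus be too small.

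**Figure D1:**
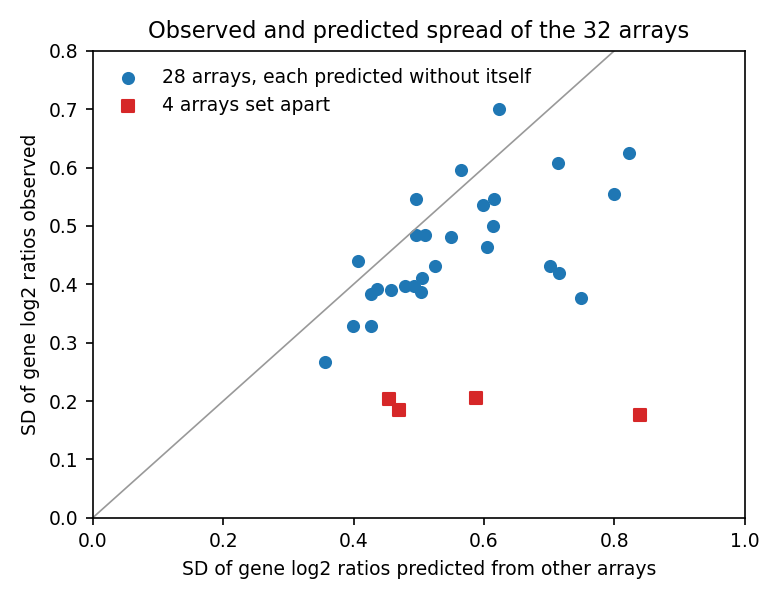
Each point is an array, with the standard deviation of its gene log2 ratios as predicted from other arrays on the x axis and as observed on the y axis, and the line marks equality. The 4 arrays set apart (squares) were observed at 0.176 to 0.205, below all of the other 28 (circles).

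The comparison of day 42 with day 0 asked which transcripts differed between prolonged near-zero growth and the chemostat. The largest increases were in the adjacent genes LLKF_0305 and LLKF_0306, to which the files give no symbol. They rose 10.7-fold (log2 change 3.42 ± 0.667, SE of the fit, n = 2 cultures per day) and 9.18-fold (3.20 ± 0.559). Each SE rests on a gene's moderated variance over all days and arrays, not on the spread of the 2 cultures on the days compared. Ribose genes rose too: rbsA, the ATPase of the ribose transporter, by a log2 change of 2.58 ± 0.418, the ribose operon regulator rbsR 4.99-fold (2.32 ± 0.302) and the ribokinase gene rbsK, outside the 10 largest increases, 4.02-fold (2.01 ± 0.334). Genes of protein quality control rose as well. The gene of HrcA, the repressor of the main chaperone operons, rose 5.90-fold (hrcA, 2.56 ± 0.454), the disaggregase gene clpB 5.71-fold (2.51 ± 0.586) and grpE, the nucleotide exchange factor of DnaK and also outside the 10 largest, 4.34-fold (2.12 ± 0.409). The other genes among the 10 largest increases were napC (5.19-fold), LLKF_2263 (4.85-fold), rmaB (4.78-fold) and pmrB (4.65-fold). The 1 gene called lower was nadR, a regulator of NAD metabolism, at 1.78-fold (−0.83 ± 0.205).

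In limma, 26 genes were higher and 1 was lower at an adjusted p below 0.05, out of 2770. Over the 28 arrays, 107 genes were higher and 98 lower, and all 27 genes called over 32 arrays were among them. In that fit LLKF_0305 was 22.8-fold higher (4.51 ± 0.544) and clpB 10.6-fold (3.40 ± 0.264). The adjacent genes yrfA and yrfB, which were not called over 32 arrays (adjusted p = 0.147 and 0.0945), rose in it by log2 changes of 4.00 ± 0.365 and 3.94 ± 0.296. Among the 10 largest decreases over the 28 arrays were genes from pksA to LLKF_1226, a locus whose symbols stand for polyketide and nonribosomal peptide synthesis. LLKF_1219 was 4.81-fold lower (−2.27 ± 0.441) and pksA 4.26-fold (−2.09 ± 0.314). The oligopeptide transport genes optB and optF were 4.32-fold (−2.11 ± 0.433) and 4.16-fold (−2.06 ± 0.392) lower in that fit. The other genes among its 10 largest increases were LLKF_0306, ynfG, LLKF_1574, hrcA, yweE and LLKF_2265, and among its decreases LLKF_1223, LLKF_1224, LLKF_1225, LLKF_1226, yrjD and LLKF_1922.

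Of 31 gene lists fixed before the data were examined, 9 passed their test on day 42. Sugar and polyol catabolism outside the phosphotransferase system rose as a group (adjusted p = 3.48e-08, and adjusted p = 0.0973 with an estimated correlation). Of its 90 members 7 were higher, 0 lower and 83 not called, and 10 were higher adjusted over the list alone, led by rbsA, rbsK and rbsR. Chaperones and Clp proteases rose (adjusted p = 8.72e-05, and adjusted p = 0.336 with an estimated correlation), with 5 of 17 members higher and 12 not called, and 6 higher adjusted over the list alone. Their median was 0.76 in retentostat 1 and 0.11 in retentostat 2, a difference that was not tested. Fatty acid synthesis genes were lower as a group (median −0.68, adjusted p = 9.34e-05, and adjusted p = 0.336 with an estimated correlation), although 0 of the 15 members were called. Its gene accC, a subunit of acetyl-CoA carboxylase, stood at −1.20 ± 0.410 and accB at −1.15 ± 0.439. In the fit without the 4 arrays 9 of the 15 fell and the median was −1.38. In that fit 13 lists passed and 6 of them held with an estimated correlation: fatty acid synthesis (adjusted p = 0.00307), sugar and polyol catabolism, other amino acid synthesis, peptide uptake and polysaccharide synthesis (adjusted p = 0.0239 for each) and chaperones (adjusted p = 0.0443). Genes of amino acid synthesis other than histidine, arginine and branched chains were lower as a group (49 members, 0 called, median −0.31, adjusted p = 0.000829, and adjusted p = 0.336 with an estimated correlation). Peptide uptake and peptidases were also lower (33 members, 0 called, adjusted p = 0.0138, and adjusted p = 0.336 with an estimated correlation). So were histidine synthesis (10 members, 0 called, adjusted p = 0.0225, and adjusted p = 0.561 with an estimated correlation) and polysaccharide synthesis (23 members, 0 called, adjusted p = 0.0206, and adjusted p = 0.719 with an estimated correlation). The ribonucleotide reductases were higher (6 members, 0 called, 2 higher adjusted over the list alone, adjusted p = 0.0249, and adjusted p = 0.548 with an estimated correlation). The anaerobic enzyme's genes nrdD and nrdG stood at 1.98 ± 0.578 and 1.99 ± 0.571. Phosphotransferase sugar uptake was higher (adjusted p = 0.0384, and adjusted p = 0.589 with an estimated correlation), and of 13 members 1 was called, the sucrose transporter gene scrA, 2.55-fold higher (1.35 ± 0.284), and 2 adjusted over the list alone. Day 42 also differed from day 0 by probe position, by −0.11 log2 per 1000 bases along a gene (interval −0.148 to −0.0733), and by −0.16 (−0.223 to −0.114) over the 28 arrays. With median centring 4 of the 9 lists no longer passed: chaperones (adjusted p = 0.0866), histidine synthesis (0.128), ribonucleotide reductases (0.144) and phosphotransferase uptake (0.331). The count of 27 genes became 2 with a dye term for each slide, 6 with median centring, 16 without day 0 of retentostat 2, 329 in a fit that takes each RNA sample's estimate as 1 value and 263 with array weights, against 27 with retentostat as a block. The array weights were fitted with a convergence warning.

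**Figure D2:**
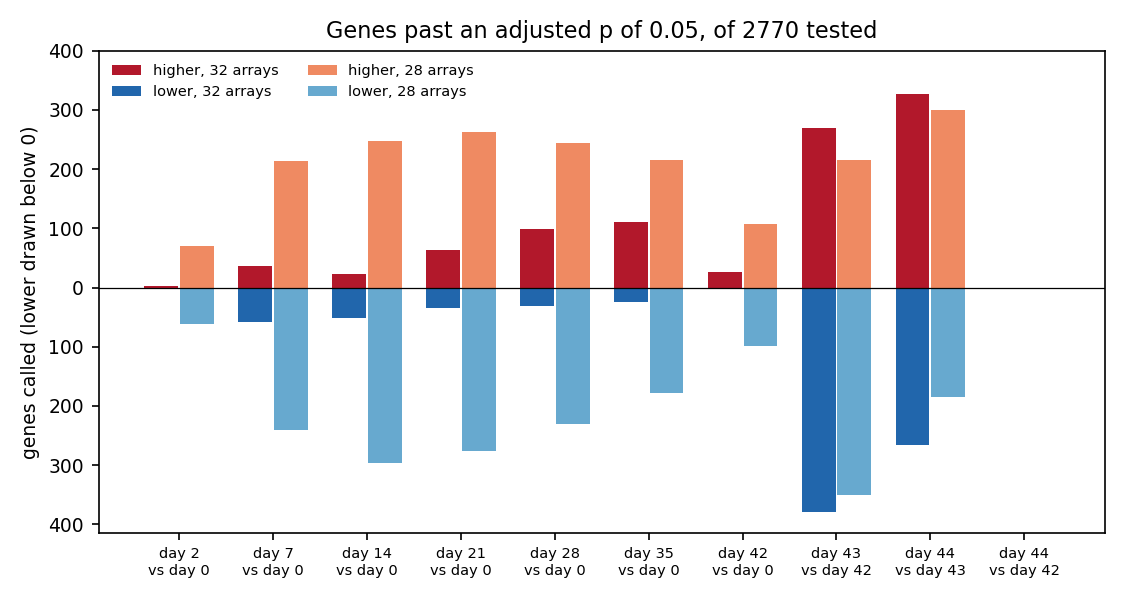
Bars show the number of genes past an adjusted p of 0.05 for each pair of days, higher genes above 0 and lower genes below, for the fits over 32 arrays (dark) and 28 arrays (light). Day 43 vs day 42 had 269 higher and 379 lower over 32 arrays, and day 44 vs day 42 had none in either fit.

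Day 2 against day 0 addressed the first change after the outflow was filtered. The prophage gene pp159 rose 4.38-fold (2.13 ± 0.454, with 0.99 in retentostat 1 and 3.25 in retentostat 2), ribG of riboflavin synthesis 2.53-fold (1.34 ± 0.283) and ynaE 2.15-fold (1.10 ± 0.219), each at an adjusted p of 0.0464. The gene dltC, which encodes the carrier protein for D-alanine on its way to teichoic acids, fell 1.72-fold (−0.78 ± 0.163, adjusted p = 0.0464). The next gene by p, hisF of histidine synthesis, was at −0.64 ± 0.141 and did not pass (adjusted p = 0.0538). Over 32 arrays 3 genes were higher and 1 lower, against 70 higher and 61 lower over the 28 arrays. In the fit over 28 arrays LLKF_1574, LLKF_1777, rpsU and LLKF_2285 (cspB) were among the 5 largest increases, and yrjC, optF, LLKF_0094, yrjD and LLKF_0684 were the largest decreases.

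On day 2, 11 of the 31 lists passed the test, and 4 of them held with an estimated correlation, all of them lower. Histidine synthesis had 10 of 10 members below 0 (median −0.51, 0 called, 8 lower adjusted over the list alone, adjusted p = 0.0323 with an estimated correlation). Other amino acid synthesis had 0 of 49 members called and 5 lower adjusted over the list alone (median −0.28, adjusted p = 0.0323 with an estimated correlation). Peptide uptake and peptidases had 0 of 33 called (median −0.17, adjusted p = 0.0347 with an estimated correlation), and D-alanylation of teichoic acids had 1 of 5 lower, 2 adjusted over the list alone (adjusted p = 0.0323 with an estimated correlation). Cold shock proteins, small RNA chaperones, were higher as a group (median 1.15, 0 of 9 called, 6 higher adjusted over the list alone, adjusted p = 5.14e-06, and adjusted p = 0.136 with an estimated correlation). Their genes cspE and cspD stood at 1.18 ± 0.309 and 1.17 ± 0.400. Oxidative stress and thioredoxin genes were higher (median 0.45, 0 of 12 called, 5 higher adjusted over the list alone, adjusted p = 0.000477, and adjusted p = 0.136 with an estimated correlation). Among them the iron-storing DNA-binding protein gene dpsA was at 1.13 ± 0.309. Translation factors and tRNA synthetases were lower (median −0.24, 0 of 34 called, adjusted p = 1.28e-05, and adjusted p = 0.119 with an estimated correlation). Pyrimidine synthesis was lower (median −0.35, 0 of 13 called, with −0.11 in retentostat 1 and −0.49 in retentostat 2, 6 lower adjusted over the list alone, adjusted p = 2.22e-05, and adjusted p = 0.0552 with an estimated correlation). Branched-chain amino acid synthesis was lower too (median −0.49, 0 of 10 called, adjusted p = 0.000477, and adjusted p = 0.335 with an estimated correlation). The F1F0 ATPase (median −0.23, with −0.40 in retentostat 1 and −0.04 in retentostat 2, 0 of 8 called, adjusted p = 0.00923, and adjusted p = 0.415 with an estimated correlation) and polysaccharide synthesis (median −0.18, 0 of 23 called, adjusted p = 0.00923, and adjusted p = 0.516 with an estimated correlation) were lower as well. Over the 28 arrays 12 lists passed and 8 held with an estimated correlation, cold shock proteins among them (6 of 9 higher, adjusted p = 0.0404). The count of 4 genes became 26 with retentostat as a block, and 0 with median centring, with a dye term for each slide, on slide 3 alone, with the authors' ratios, and without day 0 of retentostat 1.

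Across days 0 to 42, the genes with the largest F were yhbF (F = 23.2), rbsR (21.8), hemG (17.4), the sucrose-6-phosphate hydrolase gene scrB (15.6) and LLKF_0294 (14.8). The adjacent genes hemG and yhbF lay within 0.63 of day 0 up to day 14 in both cultures (log2 against the day 0 mean). On day 28 hemG stood at 3.15 in retentostat 1 and 3.17 in retentostat 2, and yhbF at 3.04 and 2.97. The gene scrB peaked on day 35, at 1.76 and 1.99. In limma 128 genes passed this test over 32 arrays and 495 over the 28, and 147 with retentostat as a block. Over the 28 arrays the largest F belonged to yrfB (71.6), LLKF_1225 (56.3), clpB (55.3), yrfA (46.6) and LLKF_1226 (44.2). By day against day 0, 36 genes were higher and 59 lower on day 7, 23 and 52 on day 14, 63 and 35 on day 21, 99 and 31 on day 28, and 110 and 24 on day 35. Without the 4 arrays these were 213 and 241, 248 and 296, 263 and 276, 245 and 230, and 216 and 179. The 95 genes of day 7 became 3 without day 7 of retentostat 2, and without day 0 of retentostat 2 their balance turned to 68 higher and 30 lower. On slide 3 alone 28 genes were called on day 7 and 5 on day 14, and with a dye term for each slide the 75 genes of day 14 became 0.

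**Figure D3:**
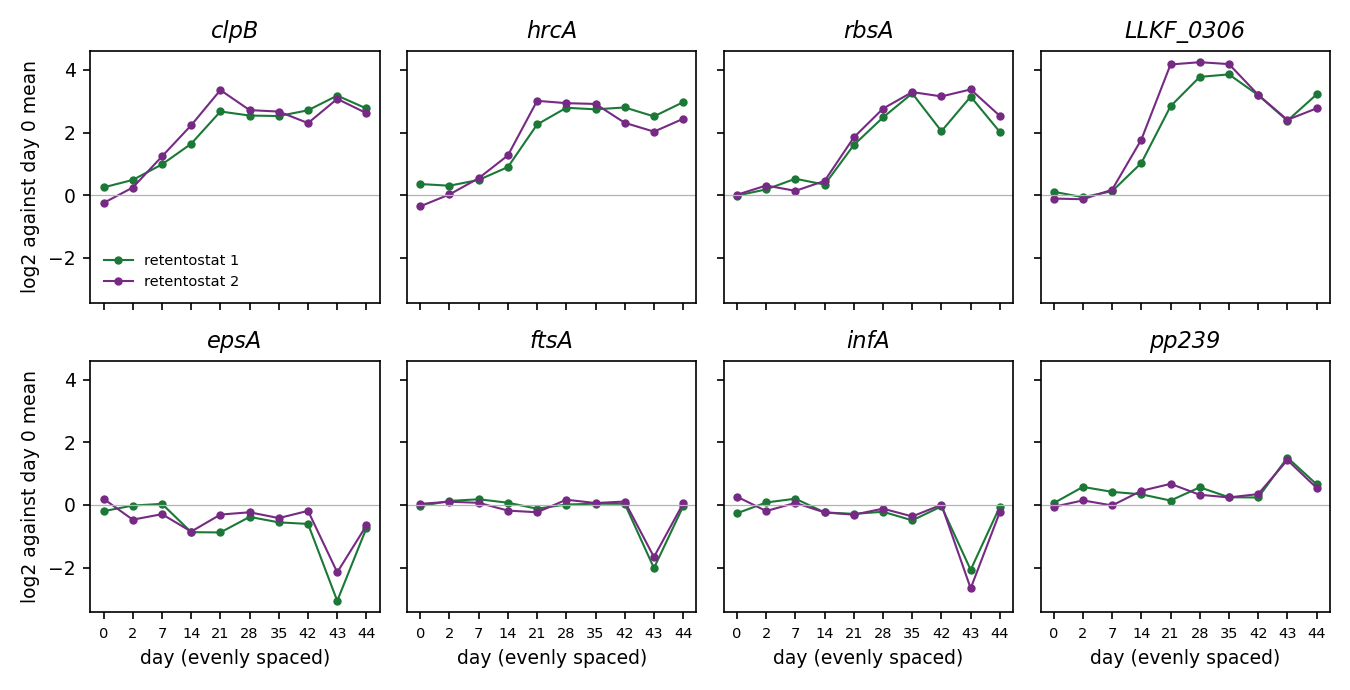
Lines show the log2 level of 8 named genes against the day 0 mean (y axis) by sampling day (x axis, evenly spaced) in retentostat 1 and retentostat 2, over 32 arrays. In this plot rbsA and hrcA stay high from day 21, while epsA, ftsA and infA drop on day 43 alone.

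Days 43 and 44 followed day 42 by single days. The labels give only the day. That the medium supply was stopped and then resumed over this time comes from general knowledge of the study, and no source used here states it. From day 42 to day 43, genes for some ribosomal proteins, initiation factors and division proteins fell. LLKF_0059 (rpmG, ribosomal protein L33) fell 6.55-fold (−2.71 ± 0.415), rpmE (L31) 5.37-fold (−2.43 ± 0.452) and rpmF (L32) 5.07-fold (−2.34 ± 0.350). The initiation factor genes infA and infC fell 5.10-fold (−2.35 ± 0.250) and 3.95-fold (−1.98 ± 0.270), and ftsA and ftsZ, whose products form the division ring, 3.77-fold (−1.91 ± 0.153) and 2.91-fold (−1.54 ± 0.178). The exopolysaccharide gene epsA fell 4.63-fold (−2.21 ± 0.321), and yrjG 6.69-fold (−2.74 ± 0.389), the largest decrease. The genes ytdF (4.56-fold), rpmJ (3.94-fold) and yacB (3.85-fold) completed the 10 largest decreases. Upward, LLKF_2239 rose 10.6-fold (3.40 ± 0.757), LLKF_1094 3.36-fold (1.75 ± 0.316) and the seryl-tRNA synthetase gene serS 3.28-fold (1.71 ± 0.339). The gene ygdA rose 3.28-fold (1.71 ± 0.326) and the prophage gene pp220 2.72-fold (1.44 ± 0.407), and the other 5 of the 10 largest increases were open reading frames without a locus number, 2.56-fold to 3.09-fold. Over 32 arrays 269 genes were higher and 379 lower, and over the 28 arrays 215 and 350. Only 1 array per culture paired day 43 with day 42. That of retentostat 1 had the largest spread between probes of a gene of the 32 arrays (SD 0.592). In Cy5, 70.8% of its gene probes exceeded the blank features. None of the 4 arrays set apart holds day 43. Over all genes the changes had a median of 0.042 and an SD of 0.572 in both fits. The 28 arrays are thus no separate check of these changes.

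Of the 31 lists, 9 passed the test between days 42 and 43, and 0 of the 9 held with an estimated correlation. Polysaccharide synthesis fell, with 15 of 23 members lower, 1 higher and 7 not called, and 17 lower and 1 higher adjusted over the list alone (median −0.85, adjusted p = 5.32e-07, and adjusted p = 0.168 with an estimated correlation, or 0.0188 over the 28 arrays). Cell division and peptidoglycan genes fell, 17 of 35 lower, 2 higher and 16 not called, and 19 lower and 2 higher adjusted over the list alone (adjusted p = 3.97e-06, and adjusted p = 0.153 with an estimated correlation). Of 56 ribosomal protein genes, 22 were lower, 2 higher and 32 not called, and 25 were lower and 4 higher adjusted over the list alone (median −0.51, adjusted p = 5.24e-05, and adjusted p = 0.396 with an estimated correlation). Translation factors and tRNA synthetases did not pass (adjusted p = 0.797), with 4 of 34 higher and 6 lower. DNA replication genes fell, 8 of 22 lower and 14 not called, and 9 adjusted over the list alone (adjusted p = 0.00029, and adjusted p = 0.153 with an estimated correlation). Among them, the sliding clamp gene dnaN fell 2.19-fold (−1.13 ± 0.185) and topA of DNA topoisomerase I 2.07-fold (−1.05 ± 0.163). The F1F0 ATPase fell with 3 of 8 members, also 3 adjusted over the list alone (adjusted p = 0.0167, and adjusted p = 0.54 with an estimated correlation), and its gene atpE was 2.06-fold lower (−1.04 ± 0.183). Prophage genes rose, with 50 of 169 higher, 6 lower and 113 not called, and 59 higher and 7 lower adjusted over the list alone (median 0.40, adjusted p = 5.32e-07, and adjusted p = 0.259 with an estimated correlation). Within them pp239 was 2.27-fold higher (1.18 ± 0.213) and pp216 2.63-fold lower (−1.40 ± 0.221). Purine synthesis rose with 4 of 18 members, also 4 adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.153 with an estimated correlation), led by purM at 2.13-fold (1.09 ± 0.241). Competence genes rose with 3 of 15 members, 2 adjusted over the list alone (adjusted p = 0.0198, and adjusted p = 0.153 with an estimated correlation), led by comGA at 1.73-fold (0.79 ± 0.177). Sugar and polyol catabolism rose with 19 of 90 members while 3 fell, 19 and 4 adjusted over the list alone (adjusted p = 0.0198, adjusted p = 0.54 with an estimated correlation, and 0.623 with median centring). Its 2 smallest p-values belonged to members that fell, the regulator genes bglR (−1.67 ± 0.290) and uxaR (−1.11 ± 0.193).

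Day 43 also differed from day 42 by brightness and by probe position, over all genes. The median change was 0.18 in the 277 dimmest genes and −0.26 in the 277 brightest, and on average 0.15 in random lists as dim as the prophage genes. The change increased by 0.23 log2 per 1000 bases of probe position along a gene (interval 0.186 to 0.276 over 2120 genes). The largest SDs between probes of a gene, 0.592, 0.507 and 0.484, were on arrays with day 43. The other arrays with day 43 stood at 0.434 and 0.411, and the median of all arrays was 0.383. Where day 43 was in Cy3, the median signal was 1013, 1030 and 1147, against a median of 2160 over all arrays. Scaling the arrays to the same spread left 111 genes, 14 higher and 97 lower, and leaving out day 42 of retentostat 1 left 318, against 658 with retentostat as a block. Slide 2 alone, whose 8 arrays hold this change in retentostat 2 and leave 1 residual degree of freedom, called 2 genes.

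Day 44 was compared with day 43, whose samples the comparison with day 42 also uses, so that opposite changes are in part built in. The genes yrjG (4.95-fold, 2.31 ± 0.389), ytdF (4.89-fold, 2.29 ± 0.179), infA (4.69-fold, 2.23 ± 0.250), rpmE (4.66-fold, 2.22 ± 0.452), yrfA (4.35-fold, 2.12 ± 0.580), epsA (3.76-fold, 1.91 ± 0.321) and ftsA (3.58-fold, 1.84 ± 0.153) rose, as did LLKF_0059 (rpmG), ytdE and ytdD. LLKF_2239 fell 4.34-fold (−2.12 ± 0.757), serS 2.83-fold (−1.50 ± 0.339), the prophage gene pp131 2.60-fold (−1.38 ± 0.330) and bglH, a 6-phospho-beta-glucosidase gene, 2.52-fold (−1.33 ± 0.325). Of these, LLKF_2239 was not called over the 28 arrays (adjusted p = 0.101). The other genes among the 10 largest decreases were ytjD (3.07-fold), LLKF_2025 (2.69-fold) and 4 open reading frames without a locus number. In all 327 genes were higher and 266 lower, against 300 and 185 over the 28 arrays. Here too 1 array per culture paired the days, and all arrays with day 44 were on slide 2. Over all genes the changes had a median of −0.039 and an SD of 0.536 in both fits. The 28 arrays are thus no separate check of them.

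Of the 10 lists past the test, 0 held with an estimated correlation. Polysaccharide synthesis rose with 13 of 23 members (17 higher and 1 lower adjusted over the list alone, median 0.90, adjusted p = 8.47e-07, and adjusted p = 0.178 with an estimated correlation, or 0.0216 over the 28 arrays). Cell division and peptidoglycan rose with 15 of 35, 1 lower (16 and 2 adjusted over the list alone, adjusted p = 2.81e-06, and adjusted p = 0.178 with an estimated correlation). Ribosomal proteins rose with 21 of 56, 3 lower (21 and 4 adjusted over the list alone, adjusted p = 3.4e-06, and adjusted p = 0.227 with an estimated correlation). DNA replication rose with 8 of 22 (8 adjusted over the list alone, adjusted p = 0.00153, and adjusted p = 0.178 with an estimated correlation), led by dnaN at 2.51-fold (1.33 ± 0.185). The F1F0 ATPase rose with 4 of 8 (7 adjusted over the list alone, adjusted p = 0.000846, and adjusted p = 0.258 with an estimated correlation). Prophage genes fell with 47 of 169, 7 higher (57 and 7 adjusted over the list alone, median −0.48, adjusted p = 8.05e-09, and adjusted p = 0.178 with an estimated correlation). Sugar and polyol catabolism fell with 15 of 90, 2 higher (15 and 2 adjusted over the list alone, adjusted p = 0.0059, adjusted p = 0.295 with an estimated correlation, and 0.182 with median centring), among them the gluconate permease gene gntP, 2.07-fold lower (−1.05 ± 0.149). Purine synthesis fell with 4 of 18 (4 adjusted over the list alone, adjusted p = 0.0216, and adjusted p = 0.178 with an estimated correlation). Histidine synthesis fell with 2 of 10 (2 adjusted over the list alone, adjusted p = 0.022, and adjusted p = 0.392 with an estimated correlation) and competence with 3 of 15 (3 adjusted over the list alone, adjusted p = 0.0497, and adjusted p = 0.178 with an estimated correlation). With retentostat as a block 592 genes were called and competence no longer passed (adjusted p = 0.0541), nor did it over the 28 arrays (0.0554). Scaling the arrays to the same spread left 70 genes, 60 higher and 10 lower, and the day 44 change tilted by −0.19 log2 per 1000 bases of probe position.

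**Figure D4:**
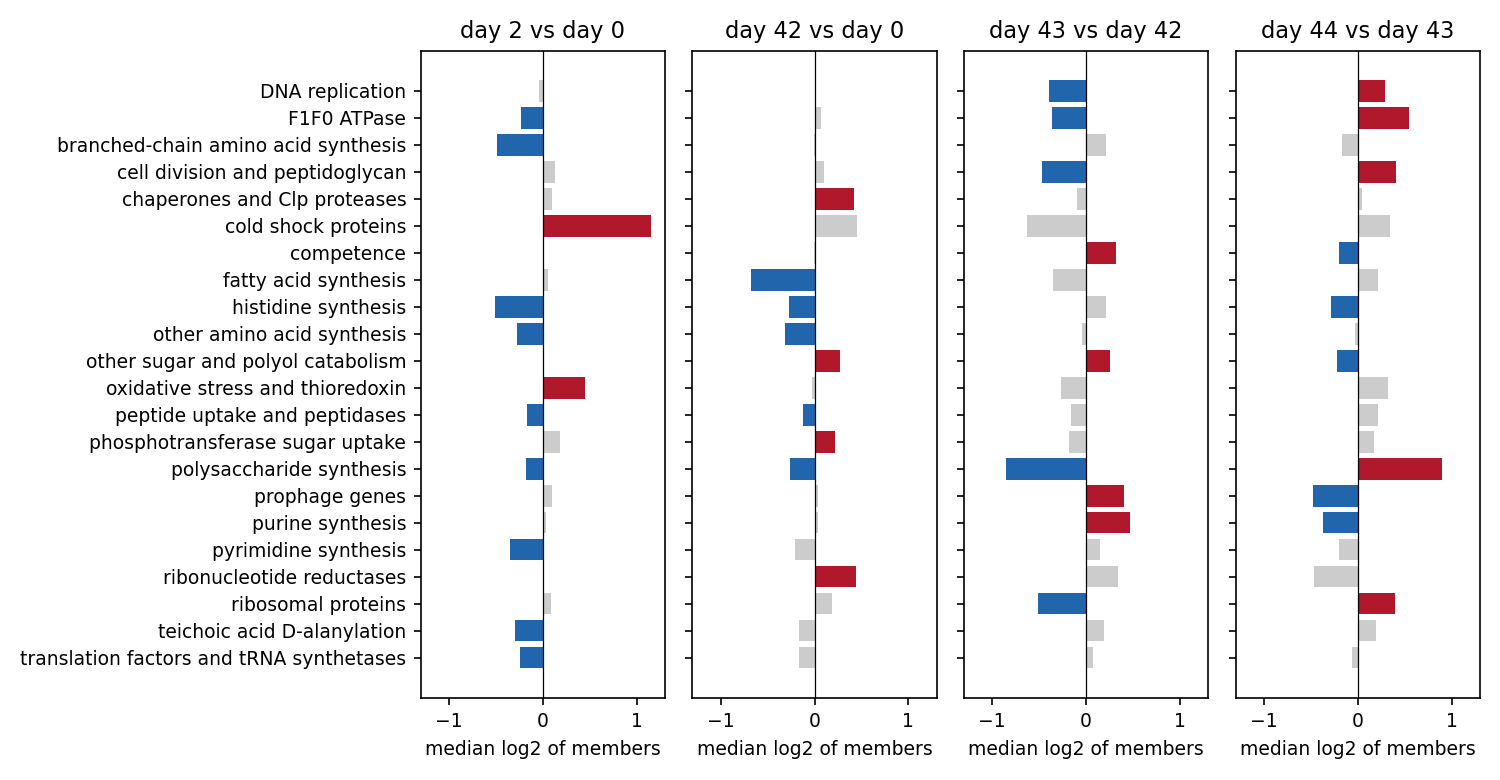
Bars show the median log2 change of the members of each gene list past its test in at least 1 of the 4 comparisons shown, red where the list was higher, blue where it was lower and grey where it did not pass. Polysaccharide synthesis stands at −0.85 on day 43 vs day 42 and at 0.90 on day 44 vs day 43.

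Changes into and out of day 43 were set against each other between cultures, so that they shared no sample. Across genes, which are not independent replicates, the day 43 change of retentostat 1 and the day 44 change of retentostat 2 correlated at −0.64, and the other crossing at −0.65, against means of 0.06 and 0.07 in simulated data without changes. The trends with brightness and probe position, which the simulation lacks, turned around between the days as well, and with the brightness trend taken out the correlations were −0.60 and −0.61. Of the 648 genes called on day 43, 643 (99.2%) had the opposite sign on day 44, against 62.9% in the simulated data, where the shared day alone gives such signs. Both changes were called for 433 genes, where 282 went down and then up, among them ftsA, infA and epsA, and 151 up and then down, among them serS and LLKF_2239. The 2 changes share the day 43 samples, and in simulated data without changes as many top-ranked genes shared 58.8 and 59.8. Independent lists of the same sizes would share 44.7 and 25.8, and the overlap includes what the shared day adds. Among the 648 genes called on day 43, the median gene came back by 0.866 of its change, against 0.198 in as many top-ranked simulated genes. This ratio also shares the day 43 samples. Between days 42 and 44, limma called 0 genes over 32 arrays and 0 over the 28. Over all genes these changes had the same median (−0.014) and SD (0.276) in both fits. An unadjusted p below 0.05 was found for 67 and 73 genes, fewer than the 138 expected by chance. In simulated data with changed genes, this comparison recovered 52 of 100 changed 2-fold and 99 of 100 changed 4-fold. The 0 calls therefore do not show that all levels had returned. A fit of 1 value per RNA sample called 6 genes and a fit without background correction 1. The smallest p-values belonged to the beta-glucoside transporter gene ptbA (−1.41 ± 0.355) and an open reading frame without a locus number (1.31 ± 0.363), followed by bglH (−1.46 ± 0.412), each with an adjusted p of 1.

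**Figure D5:**
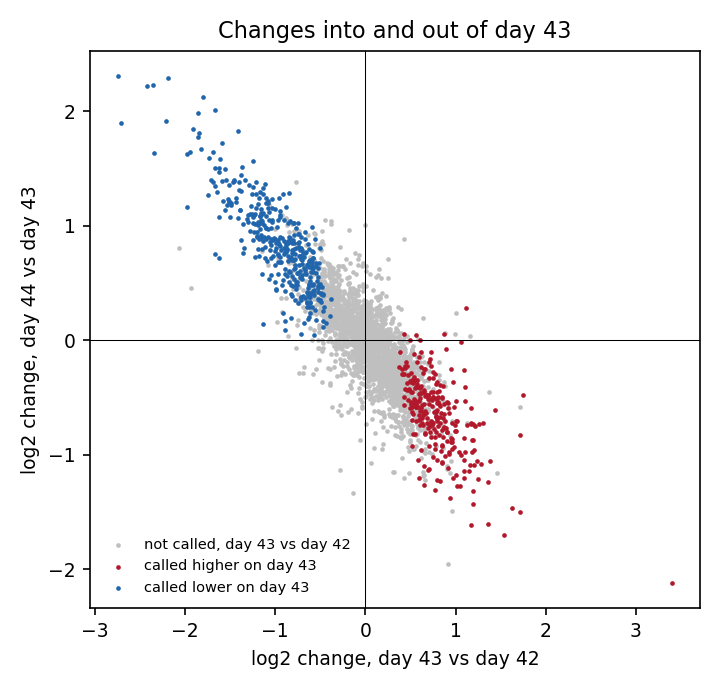
Each point is a gene, with its log2 change from day 42 to day 43 on the x axis and from day 43 to day 44 on the y axis, coloured by its call on day 43. Of the 648 called genes, 643 lie on opposite sides of 0 on the axes.

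The cultures were compared over all days, with a term for each day. The gene butA, whose product reduces diacetyl and acetoin, was 1.34-fold higher in retentostat 2 (0.42 ± 0.0777, adjusted p = 0.0329), and no other gene was called over 32 arrays. The next genes by p, LLKF_0309 (0.60 ± 0.132) and yucG (0.63 ± 0.138), each had an adjusted p of 0.101. The fit over 28 arrays called 35 genes, of which 16 were higher and 19 lower, with the glycerol genes glpK and glpD 1.68-fold (0.75 ± 0.170) and 1.67-fold (0.74 ± 0.165) higher in retentostat 2 and nrdD 1.54-fold lower (−0.62 ± 0.118). The other genes named by the rule were LLKF_0027, yucG and cstA upward and LLKF_2265, napC, nrpA and an open reading frame without a locus number downward. All 7 lists past the test were lower in retentostat 2 with 0 members called, and 0 held with an estimated correlation. They were branched-chain amino acid synthesis (median −0.25, adjusted p = 0.000119, and adjusted p = 0.321 with an estimated correlation) and cell division and peptidoglycan (adjusted p = 0.00275, and adjusted p = 0.229 with an estimated correlation). The ribonucleotide reductases (adjusted p = 0.00354, and adjusted p = 0.237 with an estimated correlation) and translation factors and tRNA synthetases (adjusted p = 0.00992, and adjusted p = 0.418 with an estimated correlation) were the next, followed by the arginine deiminase pathway (adjusted p = 0.0262, and adjusted p = 0.502 with an estimated correlation), DNA repair (adjusted p = 0.0376, and adjusted p = 0.229 with an estimated correlation) and RNA polymerase (adjusted p = 0.0405, and adjusted p = 0.229 with an estimated correlation, 1 of 9 lower adjusted over the list alone). Serial samples of 1 vessel are not independent, so these p-values describe these 2 vessels. The butA call was lost with a normexp offset of 0 (adjusted p = 0.0606), median centring (0.664), the median of probes (0.107), the authors' ratios (0.0779), a dye term for each slide (0.448), 1 value per RNA sample (0.0564), days 0 to 42 alone (0.302) and days 42 to 44 alone (0.307). Days 42 to 44 alone called 26 other genes, 2 higher and 24 lower, and with median centring RNA polymerase (adjusted p = 0.157) and DNA repair (0.193) no longer passed.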

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

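No RNA sample stood apart in the number of genes above background, in 2 groups of 10 samples tested (1 group per retentostat). That number counts a gene by any probe on any array, and does not measure how bright or noisy the arrays were. The 3 patterns weighed here were noticed in the data. The tests of the 4 arrays, of the matched lists, of the shifted list and of the first and last probes were chosen after the result was seen.

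On 4 arrays of slide 4 the ratios were narrower than on the other 28. The ratio of the SD predicted from the other arrays to the SD observed was at least 2.23 on the 4 arrays. On the 28 it was at most 1.99. It argues against a pair of RNAs that hardly differed for retentostat 1 day 14 over day 0 (4.77) and day 42 over day 21 (2.86). For the ratios of the cultures on days 28 (2.23) and 35 (2.54) it lay nearer to 1.99. Each of those RNAs was on only 2 of the 28 arrays, so for them this stays open. Dim hybridisation is argued against as well, because at least 86.9% of gene probes exceeded the blank features in Cy5, above the lowest of the 28 (62.2%). The Cy3 profile correlated better with the RNA named for Cy5 than with the RNA named for Cy3 by a median of 0.292 (0.0584 to 0.841). Among the 28 arrays the difference was above 0 on 1. It was 0.841 for day 14 over day 0 and 0.519 for day 42 over day 21, so there the Cy3 channel may have carried the RNA labelled for Cy5. For the cultures on days 28 and 35 it was 0.066 and 0.058, below the 0.198 of that 1 array, so for them this is less clear. No biological explanation was tested, and how such an exchange would have come about stays open.

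Prophage genes were higher on day 43 than on day 42 (median 0.404), a call lost with an estimated correlation (adjusted p = 0.259). Dimness as the whole cause is argued against by 0 of 10000 random lists matched on intensity with a median as high (mean 0.148, highest 0.256). At the first probe (0.308, highest 0.227) and at the last (0.386, highest 0.294), 0 of 10000 were as high, which argues against a rise at 1 end of each gene alone. Such lists leave out that neighbouring genes move together. They were also not matched on gene length, and a tilt over transcripts of several genes was not tested. With the list shifted along the gene order, which keeps neighbours together, and the trend with brightness taken out, 5 of 2424 places, the real one included, were as high as the real 0.228 (highest other 0.246). The tilt itself was there over 2120 genes, at 0.227 log2 per 1000 bases (0.186 to 0.276), 0.274 in retentostat 1 and 0.189 in retentostat 2, so day 43 RNA may have been partly degraded from one end, and how far this moved gene levels stays open. A response of the prophages to conditions on day 43, which the labels do not give, may also contribute, and the design does not separate such conditions from the day's RNA.

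The cultures differed in 1 gene over 32 arrays and in 35 over the 28. When the cultures were swapped on some of the days, 9 of 100 splits, the real one included, called at least as many genes over 32 arrays, so chance could not be excluded there, and 4 of 100 did over the 28 arrays. The highest other split called 125 genes (swapping days 21, 42 and 43) and over the 28 arrays 90 (swapping days 21, 42, 43 and 44), against the real 1 and 35. Counts so far above the real one point to a structure of the samples, which was not tested and whose cause was not found. Serial samples of 1 vessel are not independent, so these splits do not compare cultures with other cultures.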

How the results depend on the processing

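Leaving out the 4 arrays, with or without the block, fitting a slide alone and taking out the brightness trend were chosen after seeing the data. Named genes kept direction and side of the threshold in 5188 results, lost the call in 386, gained it in 356 and changed sign in 14, and named lists kept theirs in 125 and lost it in 52. For the moved counts given here the cause was not tested. Counts of genes are for days 42, 2, 7, 14, 21, 28 and 35 against day 0, day 43 against 42, day 44 against 43, the F test and the cultures, which had 27, 4, 95, 75, 98, 130, 134, 648, 593, 128 and 1 genes, and settings not given for a count left it within 1.5 times. No background correction gave 13 (day 42), 8 (day 2), 0 (day 14), 41 (day 21), 75 (day 28), 85 (day 35) and 1 for day 44 against 42, where 0 were called. A normexp offset of 0 gave 150 (day 21) and 0 (cultures). Median centring gave 6, 0, 23 (5 higher, 18 lower), 30 (2 and 28), 51 (day 21), 69 (F) and 0 (cultures), and for day 44 against 43 a split of 348 and 177. Scaling between arrays gave 14 (day 42), 0 (day 2), 111 (day 43, 14 and 97), 70 (day 44, 60 and 10) and 2 (cultures). The median of probes gave 31 (day 2) and 0 (cultures), leaving out dim probes 2 (cultures). The authors' ratios in the series matrix gave 0 (day 2), 62 (day 7), 150 (day 21, 80 and 70), 85 (F) and 0 (cultures), and splits of 26 and 6 (day 42), 142 and 404 (day 43) and 301 and 112 (day 44 against 43). One dye term per slide gave 2, 0, 0 (day 14), 26 (day 21), 55 (day 28), 53 (day 35), 69 (F) and 0 (cultures). Slide 3 alone gave 0 (day 2), 28 (day 7, 2 and 26) and 5 (day 14, 1 and 4), and slide 4 alone 0 (day 14). Slide 2 alone gave 2 (day 43), 394 (day 44 against 43, 234 and 160) and 0 (day 44 against 42). For day 44 against 43 its changes are those of the full fit (correlation 1 across genes), so that count is no separate check. These fits have fewer arrays by construction. The slide 4 fit also holds the 4 arrays set apart, among them day 14 over day 0 of retentostat 1. In limma on slide 3 alone 172 genes of day 2, and on slide 4 alone 122 of day 14, had an unadjusted p under 0.05. The replicate block gave 26 (day 2), against 27 for day 42, 82 for day 7, 74 for day 14, 99 for day 21, 141 for day 28, 145 for day 35, 658 for day 43, 592 for day 44 against 43 and 147 for F. The 2-stage fit gave 329, 31, 271, 155, 484, 663 and 670 for the days against day 0, 6 for day 44 against 42, 860 (F) and 0 (cultures). Arrays as the only error gave 65 (day 2), 144 (day 7), 177 (day 14), 83 (day 35) and 206 (F). Array weights, whose fit gave a convergence warning, gave 263, 89, 456, 594, 606, 486 and 408 for the days, 550 (F) and 3 (cultures). No moderation gave 0 (day 2), 1 (day 14) and 64 (F). A 2-fold minimum gave 54 (day 7), 203 (day 43), 181 (day 44 against 43) and 0 (cultures), by its construction. Days 0 to 42 alone gave 0 and days 42 to 44 alone 26 (2 and 24) between the cultures. Without the 4 arrays the counts were 205, 131, 454, 544, 539, 475 and 395 for the days, 495 (F) and 35 (cultures), and with the replicate block as well 219, 156, 483, 581, 587, 496 and 413, and 560 (F). With an estimated correlation the lists past the test went from 11 to 4 (day 2), from 9 to 0 (day 42), from 9 to 0 (day 43), from 10 to 0 (day 44) and from 7 to 0 (cultures). Without the 4 arrays 8 of 12 (day 2), 6 of 13 (day 42), 1 of 10 (day 43), 1 of 9 (day 44) and 0 of 11 (cultures) held with it. Median centring took the lists of day 42 from 4 higher and 5 lower to 1 and 5, of which 5 were among the 9. It also ended the calls of sugar and polyol catabolism on days 43 and 44 and of RNA polymerase and DNA repair between the cultures, and competence on day 44 was lost with the replicate block and without the 4 arrays. The reversal correlation of −0.645 was −0.851 with both changes from the same culture, which share day 43, −0.641 without the 4 arrays and −0.602 with changes adjusted for brightness.

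Leaving out 1 RNA sample at a time assumes that the lone sample of that day varies like the others. Counts ranged from 16 (without day 0 replicate 2) to 34 for day 42, and from 0 (without day 0 replicate 1 or day 2 replicate 2) to 29 (day 0 replicate 2) for day 2, with 26 without day 2 replicate 1. For day 7 they ranged from 3 (day 7 replicate 2) to 98 (day 0 replicate 2, where 36 higher and 59 lower became 68 and 30), with 59 without day 0 replicate 1. For day 14 they ranged from 0 (day 0 replicate 2 or day 14 replicate 2) to 87, with 22 without day 14 replicate 1. For day 21 they ranged from 30 (day 21 replicate 2) to 175 (day 21 replicate 1), with 37 without day 0 replicate 2. They were 81 (day 28 replicate 2) to 128 for day 28 and 66 (day 35 replicate 1) to 125 for day 35. For day 43 they were 318 (day 42 replicate 1) to 721, and for day 44 against 43 343 (day 44 replicate 1) to 656, with 360 without day 44 replicate 2, and 0 to 0 for day 44 against 42. The F test gave 77 (day 14 replicate 2) to 191, with 83 without day 35 replicate 1 and 84 without either replicate of day 28.

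Signs changed for genes that had not been called. Leaving out 1 RNA sample, nrdE on day 42 (0.35) ranged from −0.233 (without day 0 replicate 2) to 0.95, LLKF_2285 on day 42 (0.32) from −0.121 (without day 0 replicate 1) to 0.76, with −0.0262 without day 42 replicate 1, and atpH on day 2 (−0.28) from −0.65 to 0.0898 (without day 0 replicate 1). On day 42 one dye term per slide gave −0.108 for LLKF_2285, which stood at 1.43 without the 4 arrays, and −0.0763 for LLKF_0276 (0.64). On day 2, slide 3 alone gave 0.194 for atpH, 0.0827 for atpG (−0.30), 0.0217 for atpA (−0.22) and −0.0559 for hslA (1.01). Between the cultures, one dye term per slide gave 0.211 for LLKF_2220 (−0.33) and 0.00535 for fruA (−0.26), and days 42 to 44 alone gave 0.129 for parC (−0.19) and −0.432 for hslA (0.30). The cause was not tested. Signal over background limits the dim genes. Counted by any probe on any array, 2544 to 2769 of 2770 genes exceeded it in an RNA sample, and changes of the others are bounded by the background. In single Cy5 channels as few as 62.2% of gene probes exceeded the blank features, so changes of further genes may be bounded as well.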

Other observations

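Neighbouring genes were often called the same way. These runs were counted after the data had been seen. Among 2424 genes with a locus number, runs of at least 5 neighbours called in the same direction held 5 genes on day 42 against day 0, 76 genes in 11 runs on day 43 against day 42 and 99 genes in 16 runs on day 44 against day 43, while 1000 shuffles of the gene order gave at most 0, 12 and 10 genes. The run of day 42 was the ribose genes rbsC, rbsA, rbsD, rbsK and rbsR (median 2.04). Over the 28 arrays it had 6 genes with rbsB (median 2.45), and 13 neighbours from pksA onward (median −1.82) and 8 genes of fatty acid synthesis from fabD to accA (median −1.50) formed runs as well. On day 43 the longest run held 13 genes, among them rplI, dnaC, dnaB, dnaI and engA (median −1.08), and these 13 genes had a median of 1.10 on day 44 against day 43. The 9 genes from divIVA to trmH, with ftsA and ftsZ, had a median of −1.61 on day 43 and the 9 from rplQ to rplO, with infA and secY, −1.59.

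Ribosomal protein genes did not move alike on day 43. A stretch of 9 neighbours, from LLKF_2335 to LLKF_2343, was above 0 in 9 of 9 genes (0.25 to 1.11, median 0.50, with 2 called higher), while of the other 47 ribosomal protein genes 22 were called lower and 10 lay above 0 (median −0.79). The stretch was chosen after its values were seen.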
